A study of Mus musculus with 28 samples.

How the data were processed

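RNA was sequenced from mouse lung endothelial cells in 28 samples, in 2 experiments. In the first, lung endothelial cells of C57BL/6J mice were isolated without treatment or 7, 14 or 21 days after elastase, an enzyme that digests elastic fibres and brings on emphysema, with 3 libraries in each of 4 groups. In the second, mice breathed cigarette smoke in a whole-body chamber or room air for 1 or 6 months, with 4 libraries in each of 4 groups. Per the labels' protocols, the cells of the elastase experiment were purified by flow cytometry with a purity setting, and those of the smoke experiment were marked in the living mouse with an antibody to VE-cadherin before digestion and sorting. The labels name polyA-selected libraries that do not keep strand, read as pairs of 51 bp, for the elastase experiment, and either such a kit or a strand-keeping one for the smoke experiment, without saying which library had which.

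The FPKM values of the elastase experiment (fragments scaled to transcript length and to all mapped fragments) are as deposited, with 1 column per library. The submitters' processing notes name bcl2fastq 2.17, FastQC 0.11.5, Trimmomatic 0.36, TopHat2 2.1.0, HTSeq 0.11.1 and Cufflinks 2.2.1 and the build mm10 for these samples, without the role of each. The counts of the smoke experiment are whole read counts per Ensembl gene, as deposited by the authors in a table for month 1 and another for month 6. The notes name FastQC 0.11.5, STAR 2.7.6a and the build GRCm38 for them, and the counting program and the annotation are not given in the sources used here. FPKM values are not counts and hide each library's depth, so a low FPKM cannot be given a counting error. The commonest log2 ratio of low FPKM values to those of control replicate 1 was between 0.01 and 0.33 in the other libraries. FPKM is divided by depth, so a positive ratio stands for a lower depth than that of control replicate 1. The absolute depth is unknown. Of 24346 genes with FPKM, 5598 were listed at 0 in every library. Another 58 genes had a 0 in at least 1 library and reached an FPKM above 5 elsewhere, 55 of them small RNAs or predicted genes, so a 0 there can be a failed estimate.

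The smoke and air libraries held 31775558 to 38519386 counts at month 1 and 39603513 to 48066770 at month 6. Of 52636 gene identifiers, 52403 were matched to a symbol, and no entry lacked a gene identifier. Coordinates come from the GENCODE M21 annotation of GRCm38 and are counted from 1. All replicate pairs of the smoke experiment differed by more than the noise of read counting (chi-square per gene 28.9 to 124.5), so none looks like 1 library deposited again. Repeat libraries of 1 sample would differ in this way too, so the test does not show that the samples are independent. Each library counted as 1 replicate, as labelled. The labels do not say which libraries come from separate mice, so p-values measure the spread between these samples, part of which may be technical. With an unstated strand setting and counter, members of gene families with near-identical copies and overlapping genes are uncertain.

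Elastase groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, over 12066 genes with an FPKM of at least 1 in at least 3 libraries. All 12 libraries entered 1 fit and shared its estimate of the spread. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Smoke and air were compared within each month with edgeR 4.0.16, by its quasi-likelihood F test with TMM normalization and filterByExpr, and the difference of the smoke effects of the 2 months was tested in a fit of all 16 libraries. Levels in the smoke experiment are CPM, computed from those counts. They are scaled to the library total of the genes that filterByExpr kept, adjusted by the TMM factor. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. The biological coefficient of variation was 0.445 at month 1 and 0.258 at month 6.

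Before the data were examined, 32 gene lists were fixed, covering endothelial programs, stress and immune responses, metabolism, matrix, and markers of 8 other cell types. Each list with at least 3 measured genes was tested with camera (limma) at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. With the correlation estimated from the data instead, only the list of targets of AHR, the aryl hydrocarbon receptor, passed, at month 1 and in the difference between months. Of the 498 list genes, 494 were found in the FPKM table. Up to 200 genes that passed in an elastase comparison, per direction, were tested in the smoke comparisons in the same way.

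The genes named were set by a rule fixed before the data were examined. It takes, per comparison with control or air, the 8 highest and the 8 lowest fold changes among genes past the threshold with a mean of at least 2 FPKM or CPM in the higher group and no overlap between the libraries of both groups, leaving out predicted genes. It adds up to 4 members of each list by smallest p and, always, Lrg1, Cdh5, Pecam1, Kdr and Vegfa, with Cyp1a1 and Cyp1b1 for smoke. Between days and between months it takes 5 per direction.

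Replicate numbers are shared between groups. At month 6, libraries of smoke and air with the same number deviated together from their group means (correlation 0.23 to 0.59, and 8 of 8 libraries correlated best with their own number), so the fit with the number as a block is given beside that comparison where it changes a call. This pairing comes from the data, not the labels. Column names place control and day 7 on lane 5 and days 14 and 21 on lane 6, month 1 on lane 4 and month 6 on lane 1, so lane and group cannot be told apart between those sets.

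The tests were tried on simulated data with 200 changed genes per comparison. The changed genes were drawn above a minimum mean level, so the shares found do not cover low genes. For day 7 against control, limma found 92% of genes changed 2-fold and 96% of those changed 4-fold over 11954 genes, with 3.6% false calls; for day 14 it found 91% and 100%, and for day 21 92% and 98%. For day 14 against day 7 it found 94% and 99%, with 8.1% false calls, and for day 21 against day 14 93% and 96%. edgeR found 71% and 84% at month 1 over 13870 genes, 79% and 92% at month 6 over 15157 genes, and 46% and 81% for the difference between months over 15765 genes, with 2.8 to 5.2% false calls. DESeq2 1.42.0, run as an alternative, gave 17.9 to 20.2% false calls in the same data. The simulated counts used the spread that edgeR had estimated, which may favour edgeR. camera found the 1 raised list and none of the others in a simulation of day 7 with 30 lists. The simulated genes varied independently, so this does not test lists whose genes vary together. Alternatives covered the pseudocount, the filter on low values, quantile normalization, DESeq2 and its size factors, the libraries in the fit, the replicate block and leaving out each library in turn.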

Results

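Gene expression was measured by RNA sequencing in endothelial cells isolated from the lungs of mice, in 2 models of emphysema. The elastase experiment had untreated controls and lungs taken 7, 14 and 21 days after elastase (n = 3 libraries per group), and the smoke experiment had smoke and room air groups at months 1 and 6 (n = 4 per group). The FPKM of a library summed to 443434 to 465328 in the elastase experiment, where depth is unknown. Total counts were 31775558 to 38519386 at month 1 and 39603513 to 48066770 at month 6. Values are means ± SD of FPKM or, for smoke, of CPM. Adjusted p-values for genes come from limma in the elastase experiment and from edgeR in the smoke experiment, and those for gene lists from camera.

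The first comparison asked what had changed in lung endothelium 7 days after elastase. Genes of cell division rose together, and which of the cells in the libraries carried them was not tested. Top2a, the topoisomerase of dividing cells, stood at 12.7 ± 3.14 FPKM (SD, n = 3) against 0.969 ± 0.448 in controls (n = 3), and Birc5, an inhibitor of cell death active in mitosis, at 10.5 ± 2.30 against 0.676 ± 0.271. Lrg1, a secreted glycoprotein that acts on endothelial TGF-beta signalling (chromosome 17, 56119678 to 56122001, minus strand), rose from 30.9 ± 2.26 to 83.7 ± 6.32 FPKM (n = 3 each, log2 1.41, limma adjusted p = 3.78e-05). Matrix genes rose as well, with the basement membrane collagen Col4a2 at 466 ± 25.4 against 259 ± 26.1 and fibronectin (Fn1) at 16.5 ± 1.24 against 8.49 ± 0.710. The VE-cadherin gene Cdh5 stood at 1282 ± 50.5 against 1262 ± 52.0 (adjusted p = 0.912), and Pecam1, Kdr and Vegfa did not pass the threshold either.

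Of 12066 genes tested, 363 passed at day 7, 324 higher and 39 lower. The highest fold changes were those of Saa3, an acute-phase protein, Fam64a, Ube2c, Top2a, Birc5, Prc1, Chil3 and Ccnb2. Among genes that fell were Hsd11b1, which activates glucocorticoids (10.6 ± 2.05 against 17.9 ± 3.55), Clec4g, a C-type lectin, Ifitm1, Rab6b, Fam174b, Col12a1 and Klf7. The microRNA gene Mir6418 was listed at 0 in the 3 day 7 libraries and at 40.1, 201 and 46.7 in the controls. Of the 29 cell cycle genes measured, 26 rose (29 adjusted over the list alone), with a median log2 change of 1.82 (camera adjusted p = 3.93e-49). The adjusted p was 0.126 with an estimated correlation. Of 30 genes of extracellular matrix and elastic fibres, 11 rose (19 adjusted over the list alone), among them elastin (Eln, chromosome 5, 134702593 to 134747323, minus strand; log2 1.59, adjusted p = 0.0209), Col18a1 and Col15a1. Their median was 0.51 (camera adjusted p = 8.52e-12, and adjusted p = 0.413 with an estimated correlation). Of 17 matrix proteases and inhibitors, 5 rose (6 adjusted over the list alone), including the inhibitor Timp1 (4.51 ± 1.07 against 1.37 ± 0.240) and the proteases Mmp2, Mmp14 and Ctsk, with camera adjusted p = 0.00282 and adjusted p = 0.338 with an estimated correlation. Genes of aerocytes, the large alveolar capillary cells, lay lower as a group (median -0.19, camera adjusted p = 0.00282, adjusted p = 0.77 with an estimated correlation), with 0 of 12 past the threshold alone and 2 lower when adjusted over the list alone.

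Markers of other cell types were present and moved at day 7. Macrophage markers rose as a group (median 0.90, camera adjusted p = 3.54e-07, adjusted p = 0.413 with an estimated correlation). The 2 of 12 that passed were Chil3, a chitinase-like protein of alveolar macrophages (53.1 ± 23.4 against 7.25 ± 2.71), and Cd68, while 10 passed when adjusted over the list alone. Fibroblast markers had a median of -0.05 (camera adjusted p = 0.764), with 3 of 12 higher, and mural cell markers a median of -0.31 (adjusted p = 0.174). Replicate 3 of day 7 stood apart, with Saa3 at 55.5 FPKM against 4.46 and 6.35 in the other libraries, the interferon-induced chemokine Cxcl9 at 27.1 against 0.290 and 0.521, and the MHC class II chain Cd74 at 4600 against 417 and 430. Without that library 155 genes passed, 153 higher and 2 lower, and without day 7 replicate 2 183 passed. MHC class I genes then had a median of -0.26 (adjusted p = 1.72e-05) and MHC class II genes of -0.81 (adjusted p = 0.00109) without replicate 3, against positive medians of 0.14 and 0.20 that did not pass with all libraries. The small rise of glycolysis genes (median 0.17, 0 of 16 past alone and 2 adjusted over the list alone, camera adjusted p = 0.0177, adjusted p = 0.943 with an estimated correlation) was lost without replicate 3 (adjusted p = 0.334). With only both groups in the fit, 224 genes passed, and quantile normalization gave 308 higher and 97 lower genes, a share of 76% higher against 89.3%.

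Some named genes at day 7 rested on single libraries. Saa3 lost its call without control replicate 1 (0.0521) or 2 (0.0537). Of the 8 lower genes named, Rab6b kept its call without any 1 library. Clec4g, Hsd11b1, Ifitm1, Fam174b, Col12a1, Klf7 and Mir6418 lost theirs without control replicate 3 (adjusted p of 0.0666 to 0.113), day 7 replicate 2 (0.0713 to 0.114) or day 7 replicate 3 (0.0989 to 0.153). Some of them also lost it without control replicate 1 (0.062 to 0.113), control replicate 2 (0.088 to 0.122) or day 7 replicate 1 (0.0548 to 0.075). With only both groups in the fit, Saa3 (0.123), Hsd11b1 (0.155), Col12a1 (0.0825), Fam174b (0.0593) and Klf7 (0.0572) lost their calls. Hsd11b1, Fam174b, Col12a1 and Mir6418 lost theirs with no filter on low values (0.0531 to 0.0591), and Clec4g, Ifitm1, Col12a1, Klf7 and Mir6418 with the mean of 9 fibroblast markers outside the matrix list as a covariate (0.0585 to 0.0933). With 6 of these markers that encode no matrix protein, 206 genes passed, 197 higher and 9 lower, and Saa3 and all the lower genes named but Rab6b lost their calls (0.131 to 0.239). Both covariates were chosen after the data were seen. Besides Mfap5, which is on the matrix list, they left out the collagen genes Col1a1 and Col1a2, which are not on it. With the 6 markers the folds of these genes were 0.54 to 1.07 times those without a covariate, lowest for Hsd11b1 and Fam174b.

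**Figure D1:**
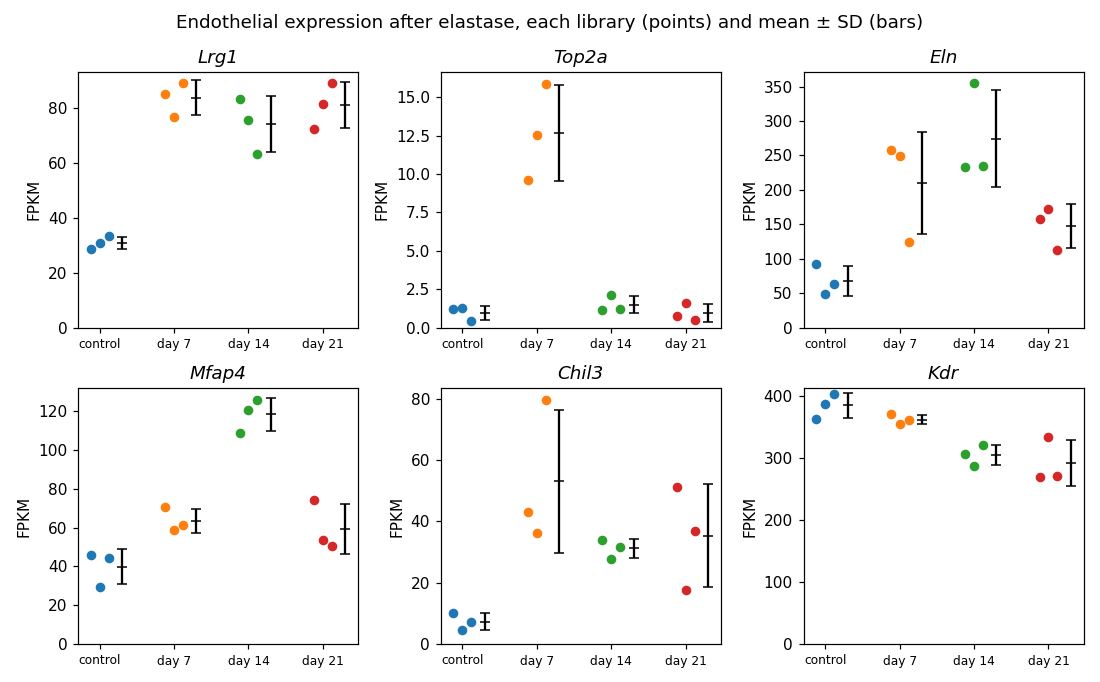
FPKM of Lrg1, Top2a, Eln, Mfap4, Chil3 and Kdr in each library of the 4 elastase groups (points), with group means and SD (n = 3); each panel has its own vertical axis. Lrg1 was above the controls at all 3 times, whereas Top2a was high at day 7 and stood at 1.50 ± 0.535 at day 14.

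At day 14 genes of elastic fibres and matrix were among those that rose. Elastin reached 274 ± 70.5 FPKM against 67.8 ± 21.9 in controls (n = 3 each, log2 2.02, limma adjusted p = 0.0254). The microfibril-associated genes Mfap4 and Mfap5 rose to 118 ± 8.58 from 39.8 ± 9.04 and to 8.68 ± 1.58 from 2.09 ± 0.768, and Col3a1 to 30.1 ± 1.09 from 11.2 ± 2.12. Lrg1 stood at 74.1 ± 10.1 (log2 1.23, adjusted p = 0.00306). Chil3, the chemokine Ccl6, Prnd and Vwa1 also rose, and Clec4g, Fndc1, Ifltd1, Col12a1, Tmeff2, Fmo4, Fam102b and Rgs9 fell. Cdh5, Pecam1, Kdr and Vegfa did not pass.

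In all 126 genes passed at day 14, 75 higher and 51 lower. Matrix genes rose as a list, with 13 of 30 higher (21 adjusted over the list alone) and a median of 0.57 (camera adjusted p = 8.15e-18, adjusted p = 0.248 with an estimated correlation). Fibroblast markers rose by a similar amount, with 4 of 12 higher (8 adjusted over the list alone), a median of 0.60 and camera adjusted p = 2.65e-09 (adjusted p = 0.248 with an estimated correlation). They included the fibroblast transcription factor Tcf21 at 17.0 ± 1.61 against 9.66 ± 1.71 FPKM and Col1a2 at 20.5 ± 0.337 against 8.95 ± 1.62. Macrophage markers were higher as a list (1 of 12 past, Chil3; 2 adjusted over the list alone; camera adjusted p = 1.67e-05, adjusted p = 0.38 with an estimated correlation). Lung epithelial and mural markers also lay higher (medians 0.58 and 0.24, camera adjusted p = 0.00562 and 0.029, each adjusted p = 0.909 with an estimated correlation). The epithelial call was lost without control replicate 1 (0.0571), control replicate 2 (0.0556) or day 14 replicate 1 (0.0895), and the mural call without control replicate 2 (0.118) or day 14 replicate 1 (0.222). Among matrix proteases and inhibitors 2 of 17 rose, Mmp2 and Timp1, and 1 fell, the plasminogen activator Plau (8 and 2 adjusted over the list alone; camera adjusted p = 0.00226, adjusted p = 0.248 with an estimated correlation). Aerocyte genes lay lower with a median of -0.33 (camera adjusted p = 1.3e-06, adjusted p = 0.248 with an estimated correlation). None of the 12 passed alone and 9 were lower when adjusted over the list alone, among them Kdr, the main VEGF receptor, at 304 ± 16.7 against 384 ± 20.2 (adjusted p = 0.087 over all genes).

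The day 14 count rested on few libraries. It was 1 without day 14 replicate 2, 7 without day 14 replicate 3, and 8 without control replicate 2 or 3. Among the named genes only Lrg1 passed in each of these fits, with the others that lost their call at an adjusted p of 0.0535 to 0.167. Col3a1, Fndc1 and Vwa1 also lost it without control replicate 1 (0.0529 to 0.0605), and these 3, Chil3, Ccl6 and Tmeff2 without day 14 replicate 1 (0.0524 to 0.088). Without control replicate 1 the count was 146, with the majority turned to 59 higher and 87 lower. Quantile normalization gave 226 genes, 105 higher and 121 lower, and moved the share of higher genes from 59.5% to 46.5%. Fits without a filter on low values and with only both groups gave 55 and 76 genes. Without the filter Ccl6, Chil3, Col3a1, Fam102b, Fmo4, Fndc1, Ifltd1, Tmeff2 and Vwa1 lost their calls (0.0516 to 0.0762), and with only both groups Col12a1 (0.0595), Fam102b (0.0568) and Fmo4 (0.0792) did. With the mean of 9 fibroblast markers outside the matrix list as a covariate, chosen after the data were seen, limma called 0 genes (1043 at an unadjusted p under 0.05). Of these markers Dcn, Dpt and Npnt encode matrix proteins themselves, so this covariate takes out part of the matrix change. Elastin then stood at a log2 change of 1.37 (adjusted p = 0.468) and Lrg1 at 1.23 (adjusted p = 0.176). With the 6 other markers alone limma also called 0 genes (909 unadjusted), with elastin at 1.30 (adjusted p = 0.584) and Lrg1 at 1.23 (adjusted p = 0.176). The standard error of Lrg1 grew from 0.107 to 0.167 and 0.172 while its fold held, so a smaller fold was not the reason for its lost call. For Eln, Mfap4, Mfap5 and Col3a1 the folds shrank to 0.59 to 0.72 times those without a covariate. The other named genes that had passed had folds 0.71 (Fmo4) to 1.25 (Clec4g) times as large. Their standard errors were 1.4 to 1.61 times as large. Lists of lipid handling, glycolysis, NRF2 target and cell cycle genes passed with small medians of 0.31, 0.13, 0.16 and 0.15, and none of these held with an estimated correlation (adjusted p = 0.248, 0.802, 0.802 and 0.909 with an estimated correlation). The lipid call was lost without control replicate 2 (0.0556) or 3 (0.0761) or day 14 replicate 2 (0.0719), and the glycolysis call without day 14 replicate 2 (0.0526). The NRF2 call was lost without control replicate 2 (0.197) or day 14 replicate 1 (0.101), and the cell cycle call without control replicate 3 (0.123) or day 14 replicate 2 (0.159).

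At day 21 Lrg1 remained raised at 81.0 ± 8.28 FPKM (n = 3, log2 1.36, limma adjusted p = 0.00113). The matricellular gene Sparcl1 stood at 274 ± 45.3 against 135 ± 13.3, Prnd at 6.14 ± 2.99 against 0.792 ± 0.180, and Scand1, Tmem238, Grrp1, Ndufb2 and Pgp were also higher, while Clec4g fell (1.67 ± 0.372 against 4.41 ± 0.385). Cdh5, Pecam1, Kdr and Vegfa did not pass. In all 13 genes passed, 12 higher and 1 lower. Without any 1 of the control libraries or day 21 replicate 1, only Lrg1 passed. The count was 3 without day 21 replicate 2, 1 higher and 2 lower, and 60 without day 21 replicate 3. It was 4 with no filter on low values, 2 with only both groups in the fit, 1 in each direction, and 20 with a pseudocount of 0.1. With the covariate of 9 fibroblast markers it was 5, and the direction turned to 1 higher and 4 lower, with 2 of the 13 genes among them. Clec4g, Ndufb2, Pgp, Prnd, Scand1, Sparcl1 and Tmem238 lost their calls with no filter on low values (0.0726 to 0.103) and, together with Grrp1, with only both groups in the fit (0.113 to 0.228). With that covariate all of these but Clec4g lost theirs (0.0538 to 0.113), and so they did with the 6 markers that encode no matrix protein (0.0807 to 0.145), where 4 genes passed, 1 higher and 3 lower. Their folds were 0.87 to 1.06 times those without a covariate, with standard errors 1 to 1.17 times as large. For Tmem238 the folds were 0.89 and 0.87 times as large and the standard errors 1 and 1.02 times. The others that lost their calls kept at least 0.96 of their folds, so a smaller fold was not the main reason there. Quantile normalization gave 13 higher and 6 lower genes, a share of 68.4% higher against 92.3%.

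Aerocyte genes had their lowest median at day 21 (-0.35, camera adjusted p = 1.37e-10, adjusted p = 0.358 with an estimated correlation). No member passed alone and 9 of 12 were lower when adjusted over the list alone, including Ednrb, the endothelin B receptor (74.4 ± 15.0 against 117 ± 12), and Kdr (291 ± 37.2 against 384 ± 20.2). The matrix list lay higher (median 0.35, 0 of 30 past alone and 15 adjusted over the list alone, camera adjusted p = 3.27e-10, adjusted p = 0.531 with an estimated correlation). So did the glycolysis and hypoxia list (median 0.27, 0 of 16 and 7 adjusted over the list alone, camera adjusted p = 4.32e-08, adjusted p = 0.478 with an estimated correlation). Fibroblast and macrophage markers lay higher with medians of 0.26 and 0.64 (camera adjusted p = 0.000473 and 0.000445, each adjusted p = 0.572 with an estimated correlation). The fibroblast call was lost without control replicate 2 (0.224). MHC class I and interferon genes lay lower (medians -0.31 and -0.24, camera adjusted p = 0.0013 and 0.00147, adjusted p = 0.8 and 0.814 with an estimated correlation), and both calls were lost without control replicate 2 (0.226 and 0.353). Arterial genes, with the vasoconstrictor gene Edn1 at 123 ± 21.7 against 62.6 ± 14.8 (adjusted p = 0.0745), had a median of 0.30 (camera adjusted p = 0.012, adjusted p = 0.572 with an estimated correlation), which was lost without day 21 replicate 2 (0.0588). Lipid handling (median 0.27, camera adjusted p = 0.0279, adjusted p = 0.358 with an estimated correlation), oxidative phosphorylation (0.04, 0.028, adjusted p = 0.757 with an estimated correlation) and TGF-beta genes (0.07, 0.0458, adjusted p = 0.572 with an estimated correlation) lay slightly higher. Pan-endothelial genes lay lower (-0.09, 0.0344, adjusted p = 0.572 with an estimated correlation). The lipid call was lost without control replicate 2 (0.113) or day 21 replicate 3 (0.149), and that of oxidative phosphorylation without control replicate 2 (0.364) or day 21 replicate 2 (0.0655) or 3 (0.108). The TGF-beta call was lost without control replicate 1 (0.0511) or 3 (0.186) or day 21 replicate 2 (0.12) or 3 (0.138), and the pan-endothelial call without control replicate 1 (0.147) or 2 (0.353) or day 21 replicate 1 (0.263). Days 14 and 21 were sequenced in another lane than the controls, so these differences cannot be told apart from the lane.

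Between day 7 and day 14 the cell cycle genes fell back. Top2a dropped from 12.7 ± 3.14 to 1.50 ± 0.535 FPKM and the proliferation marker Mki67 from 7.21 ± 1.87 to 0.640 ± 0.0337 (n = 3 each). Of 29 cell cycle genes, 27 were lower at day 14 (29 adjusted over the list alone), with a median of -1.52 (camera adjusted p = 5.35e-46, adjusted p = 0.152 with an estimated correlation). The fibroblast-rich genes Inmt (164 ± 18.5 against 69.1 ± 17.9), Pdgfra, Npnt, Cdo1 and C7 rose. Fibroblast markers were higher in 5 of 12 (7 adjusted over the list alone; camera adjusted p = 7.51e-06, adjusted p = 0.942 with an estimated correlation). Mural and epithelial lists lay higher as well (camera adjusted p = 8.97e-05 and 0.00213, each adjusted p = 0.942 with an estimated correlation). The epithelial call was lost without day 14 replicate 1 (0.0627). In all 382 genes passed, 91 higher and 291 lower. The count was 86 without day 7 replicate 2, 114 without day 7 replicate 3, 229 without day 14 replicate 2, 165 without day 14 replicate 3 and 186 with only both groups in the fit, and day and lane cannot be told apart. Quantile normalization gave 197 higher and 302 lower genes, a share of 39.5% higher against 23.8%. Inmt lost its call without day 14 replicate 1 (0.0535) or 3 (0.0605) or day 7 replicate 2 (0.0915) or 3 (0.0852), Npnt without day 14 replicate 3 (0.0715) or day 7 replicate 2 (0.0802) or 3 (0.0772), and C7 without day 7 replicate 2 (0.0591).

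Between days 14 and 21, which shared a lane, 1 gene passed, the transcription factor Klf10, at 46.1 ± 2.57 against 27.8 ± 1.06 FPKM (n = 3 each, limma adjusted p = 0.0432), while 1277 had an unadjusted p under 0.05. The matrix list lay lower at day 21 (median -0.29, 0 of 30 past alone and 1 adjusted over the list alone, camera adjusted p = 3.64e-09, adjusted p = 0.85 with an estimated correlation), as did fibroblast markers (median -0.38, adjusted p = 8.29e-06, adjusted p = 0.85 with an estimated correlation). The same held for MHC class II genes (median -0.87, adjusted p = 0.00456, adjusted p = 0.882 with an estimated correlation) and matrix proteases and inhibitors (median -0.12, adjusted p = 0.00307, adjusted p = 0.627 with an estimated correlation). Cell cycle, interferon and epithelial genes also lay lower (medians -0.11, -0.22 and -0.50, camera adjusted p = 0.00372, 0.0114 and 0.0114, adjusted p = 0.882, 0.889 and 0.882 with an estimated correlation). The cell cycle call was lost without day 14 replicate 2 (0.143) or day 21 replicate 1 (0.0679) or 3 (0.0689). The interferon call was lost without day 14 replicate 1 (0.0772) or 3 (0.373) or day 21 replicate 3 (0.0671), and the epithelial call without day 14 replicate 1 (0.252) or day 21 replicate 3 (0.201). The Klf10 call was lost without day 14 replicate 2 (0.182) or 3 (0.395) or day 21 replicate 1 (0.265), 2 (0.116) or 3 (0.0901), and without a filter on low values (0.0799) or with only both groups in the fit (0.0728). limma called 0 genes in these fits (910 to 1650 at an unadjusted p under 0.05) except without day 21 replicate 3, where it called 2, and it called 11 without day 14 replicate 1.

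**Figure D2:**
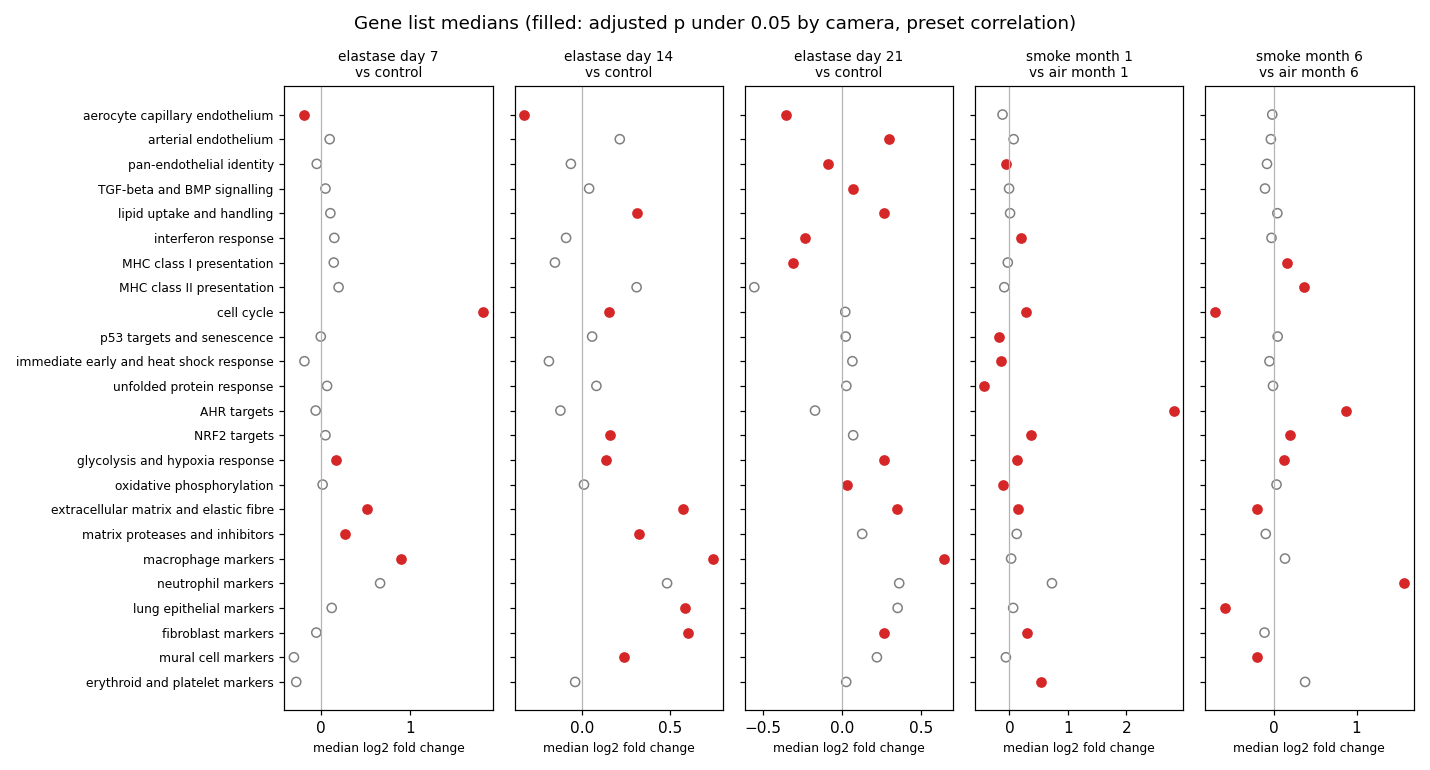
Median log2 fold change of each gene list in the 3 elastase comparisons with control and the 2 smoke comparisons with air; each panel has its own horizontal axis and filled points passed camera at an adjusted p of 0.05. The cell cycle list led at day 7 (1.82) and the AHR target list at month 1 (2.81).

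After 1 month of smoke, the genes that rose most were those of the aryl hydrocarbon receptor (AHR), a sensor of polycyclic hydrocarbons. Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824, plus strand), which oxidizes such compounds, stood at 9855 ± 1229 CPM in smoke against 81.2 ± 20.7 in air (n = 4 each, log2 6.92, edgeR adjusted p = 6.04e-11). Its relative Cyp1b1 reached 19.0 ± 7.0 against 1.80 ± 0.784, the receptor's repressor Ahrr 9.38 ± 1.67 against 0.875 ± 0.557, and the quinone reductase Nqo1 24.8 ± 3.28 against 3.73 ± 2.98. Lama1, Neurl3, Trerf1 and Tnxb also rose, and Tmtc2 fell. Lrg1 did not pass, at 75.2 ± 12.5 against 71.8 ± 18.7 (adjusted p = 0.982), and neither did Cdh5, Pecam1, Kdr or Vegfa.

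Of 14695 genes, 15 passed at month 1, 14 higher and 1 lower. Of 8 AHR targets, 4 rose (6 adjusted over the list alone), with a median of 2.81 (camera adjusted p = 2.28e-62), and this call held with an estimated correlation (adjusted p = 7.05e-05 with an estimated correlation). Targets of NRF2, the regulator of the response to oxidants, had 3 of 19 past, Txnrd1 (64.1 ± 8.11 against 33.9 ± 2.44), Nqo1 and Gclc, and 10 adjusted over the list alone (median 0.36, camera adjusted p = 6e-11, adjusted p = 0.0974 with an estimated correlation). Genes of the unfolded protein response lay lower (median -0.43, camera adjusted p = 6.52e-12, adjusted p = 0.175 with an estimated correlation). None of the 18 passed alone and 8 were lower when adjusted over the list alone, with the chaperone Hspa5 at 422 ± 139 against 755 ± 169. Erythroid and platelet markers lay higher (median 0.54, 4 of 9 adjusted over the list alone, camera adjusted p = 4.88e-06, adjusted p = 0.169 with an estimated correlation), with the haemoglobin gene Hbb-bs at 154 ± 47.7 against 72.7 ± 14.5. Fibroblast markers had a median of 0.30 (camera adjusted p = 0.000613, adjusted p = 0.137 with an estimated correlation). Without air replicate 2 or smoke replicate 3, 7 genes passed. The count was 63 with all 16 libraries in 1 fit, 65 with no filter on low counts and 86 with DESeq2, whose share of false calls was higher in simulated data. Cyp1a1 passed in each of these fits, and so did Cyp1b1 except under DESeq2, which gave it no adjusted p. Ahrr lost its call without smoke replicate 3 (0.0578), and Tmtc2 without air replicate 2 (0.105) or 4 (0.0646) or smoke replicate 3 (0.0923) or 4 (0.0539). Nqo1 lost it without air replicate 2 (0.105) or 3 (0.107) or smoke replicate 1 (0.104), 2 (0.072), 3 (0.123) or 4 (0.0718), and Neurl3 with all 16 libraries in 1 fit (0.073).

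Weaker list results at month 1 each passed with the preset correlation and not with an estimated one. Cell cycle genes had a median of 0.29 (camera adjusted p = 0.0264, adjusted p = 0.488 with an estimated correlation), lost without air replicate 1 (0.0915) or 3 (0.109) or smoke replicate 1 (0.0978) or 4 (0.0895). Interferon genes had a median of 0.20 (0.0206, adjusted p = 0.771 with an estimated correlation), lost without air replicate 3 (0.0615) or 4 (0.124) or smoke replicate 2 (0.141) or 4 (0.277). Glycolysis genes had a median of 0.13 (0.0393, adjusted p = 0.492 with an estimated correlation), lost without air replicate 1 (0.0621) or 2 (0.317) or smoke replicate 4 (0.282). Matrix genes had a median of 0.15 (0.0433, adjusted p = 0.78 with an estimated correlation), lost without air replicate 1 (0.76) or smoke replicate 1 (0.291). Oxidative phosphorylation genes lay lower (median -0.10, 0.0206, adjusted p = 0.771 with an estimated correlation), a call lost without air replicate 1 (0.218) or smoke replicate 1 (0.0787) or 3 (0.292). So did immediate early and heat shock genes (-0.15, 0.0433, adjusted p = 0.78 with an estimated correlation), lost without air replicate 1 (0.667) or 4 (0.281) or smoke replicate 2 (0.161) or 3 (0.673). The p53 targets (-0.17, 0.0205, adjusted p = 0.175 with an estimated correlation) lost their call without air replicate 1 (0.0621), and pan-endothelial genes (-0.05, 0.0206, adjusted p = 0.207 with an estimated correlation) without air replicate 2 (0.0983) or smoke replicate 2 (0.109).

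Among the genes that passed after 6 months of smoke, Dbp, Tef and Hlf, of the circadian clock's output, had the highest fold changes. The clock was not among the lists fixed before the data were examined. The transcription factor Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203, plus strand) was at 157 ± 41.5 CPM in smoke against 4.87 ± 1.62 in air (n = 4 each, log2 5.02, edgeR adjusted p = 5.81e-05). At month 1 it had been at 169 ± 14 in smoke and 119 ± 51.6 in air, so for Dbp the air group of month 6 stands apart. The months also differ in lane and may differ in library kit. Its relatives Tef and Hlf stood at 168 ± 26.0 against 20.2 ± 8.48 and at 13.6 ± 2.58 against 1.84 ± 0.720, and the clock repressors Per3 and Cry2 at 28.4 ± 1.61 against 5.05 ± 1.68 and 27.6 ± 4.24 against 10.6 ± 3.06. Cyp2a5, a member of a family with near-identical copies and so uncertain, and Tspan4 also rose, and Mmp15, Leo1, the pericyte gene Rgs5 and Nptx1 fell. Cyp1a1 stood at 384 ± 344 against 21.8 ± 6.86 (log2 4.14) and did not pass (adjusted p = 0.0844), whereas with the replicate block it did (log2 3.62, adjusted p = 0.00719). It also passed with all 16 libraries in 1 fit (0.000729), with no filter on low counts (0.00644), under DESeq2 (1.08e-06), without smoke replicate 1 (0.0489) and without replicate 1 of both groups (0.0449). Cyp1b1 stood at 2.83 ± 1.27 against 1.55 ± 0.472 (adjusted p = 0.734) and did not pass, and neither did Cdh5, Pecam1, Kdr or Vegfa. Lrg1 was at 112 ± 29.7 against 95.8 ± 29.9 (adjusted p = 0.919).

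Of 15489 genes, 11 passed at month 6, 7 higher and 4 lower, and with the replicate block 56 passed, 22 higher and 34 lower, including those 11. AHR targets lay higher (median 0.87, 0 of 7 past alone and 3 adjusted over the list alone, camera adjusted p = 7.43e-07, adjusted p = 0.079 with an estimated correlation). NRF2 targets did too (median 0.20, 4 of 19 adjusted over the list alone, camera adjusted p = 7.43e-07, adjusted p = 0.144 with an estimated correlation). Genes of MHC class II presentation lay higher (median 0.36, 0 of 10 past alone and 5 adjusted over the list alone, camera adjusted p = 1.69e-08, adjusted p = 0.079 with an estimated correlation), with H2-Ab1 at 726 ± 79.4 against 499 ± 29.2 CPM and their activator Ciita at 96.0 ± 15.6 against 58.2 ± 11.2. MHC class I genes had a median of 0.15 (camera adjusted p = 0.000499, adjusted p = 0.079 with an estimated correlation). Cell cycle genes lay lower (median -0.72, 0 of 31 past, camera adjusted p = 1.51e-06, adjusted p = 0.421 with an estimated correlation), with Top2a at 1.66 ± 0.890 against 4.88 ± 1.98. So did matrix genes (median -0.21, 3 of 30 lower adjusted over the list alone, camera adjusted p = 8.04e-06, adjusted p = 0.421 with an estimated correlation), with Col4a1 at 1529 ± 46.2 against 1931 ± 126.

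Markers of other cells moved at month 6 too. Lung epithelial markers lay lower in smoke (median -0.60, 0 of 16 past, camera adjusted p = 7.43e-07, adjusted p = 0.425 with an estimated correlation), with Sftpb at 115 ± 56.5 against 209 ± 47.2 CPM. Mural markers lay lower (median -0.21, Rgs5 past, camera adjusted p = 0.00017, adjusted p = 0.421 with an estimated correlation), a call lost without smoke replicate 2 (0.0738). Neutrophil markers lay higher (median 1.58, 0 of 7 past, camera adjusted p = 0.000698, adjusted p = 0.425 with an estimated correlation), a call lost without smoke replicate 1 (0.0731). With the replicate block, B cell (median -0.32, adjusted p = 0.0114), fibroblast (-0.19, 0.0264), matrix protease (-0.09, 0.00398) and TGF-beta genes (-0.11, 0.0426) also lay lower and vascular tone genes higher (0.12, 0.0288). None of these 5 passed with the block and an estimated correlation (adjusted p = 0.451, 0.725, 0.304, 0.55 and 0.341 with an estimated correlation). Glycolysis genes had a median of 0.12 (camera adjusted p = 0.00765, adjusted p = 0.421 with an estimated correlation), lost without air replicate 3 (0.0708) or smoke replicate 3 (0.0878). The gene count was 19 without air replicate 1, 4 without air replicate 2, 3 or 4, and 5, 6, 3 and 7 without smoke replicates 1, 2, 3 and 4; Dbp, Tef and Per3 passed in each of these fits. Hlf lost its call without air replicate 3 (0.0668) or smoke replicate 3 (0.0594). Cry2, Leo1, Mmp15, Nptx1 and Rgs5 lost theirs without any library but air replicate 1 (0.0502 to 0.229). Cyp2a5 lost its call without any but air replicate 1 and smoke replicate 2 (0.0502 to 0.112), and Tspan4 without air replicate 2 or 4 or smoke replicate 1, 2 or 3 (0.055 to 0.0966). With all 16 libraries in 1 fit, Leo1 (0.585), Mmp15 (0.581), Nptx1 (0.296), Rgs5 (0.326) and Cyp2a5 (1) lost their calls, and all 11 genes that passed were higher. The number of genes was 23 with no filter on low counts, 11 higher and 12 lower, and 128 with DESeq2, 59 higher and 69 lower. It was 20 without replicate 1 of both groups, a setting added after the data were seen, where Nptx1 lost its call (0.0647).

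**Figure D3:**
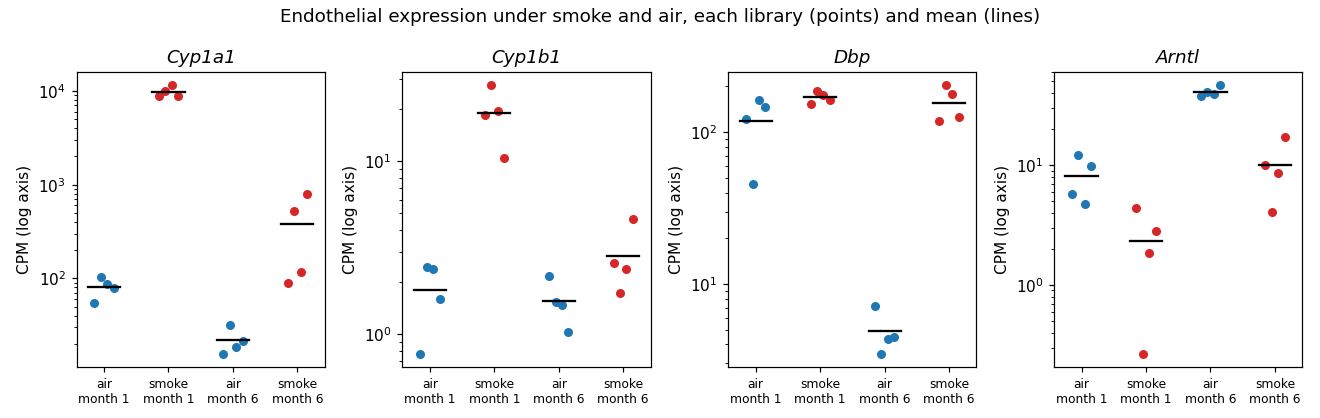
CPM of Cyp1a1, Cyp1b1, Dbp and Arntl on a log axis in each smoke and air library at months 1 and 6 (points), with the group mean as a line (n = 4). Cyp1a1 was above air in every smoke library at both months, and in Dbp the air libraries of month 6 lay far below those of the other 3 groups.

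The months differed in their smoke effect for 3 of 16337 genes, 2 higher and 1 lower at month 6. Dbp and Tef had differences of 4.51 (edgeR adjusted p = 2.75e-05) and 2.37 (adjusted p = 0.00773) on the log2 scale. Pcdhgb8 had a difference of -8.76 (adjusted p = 0.0157); it shares exons with its neighbours in the protocadherin cluster, so its count is uncertain, and it was chosen after its values were seen. AHR targets responded less at month 6 (median difference -1.93, 3 of 8 adjusted over the list alone, camera adjusted p = 4.66e-08), and this held with an estimated correlation (adjusted p = 0.002 with an estimated correlation). Genes of the unfolded protein response had a median difference of 0.50 (camera adjusted p = 2.94e-08, adjusted p = 0.288 with an estimated correlation). Oxidative phosphorylation (0.15, 0.000881, adjusted p = 0.82 with an estimated correlation), MHC class II (0.51, 0.00197, adjusted p = 0.673 with an estimated correlation) and MHC class I genes (0.14, 0.0164, adjusted p = 0.828 with an estimated correlation) had higher smoke effects at month 6. Cell cycle (-1.02, 9.3e-06, adjusted p = 0.288 with an estimated correlation), epithelial (-0.72, 5.42e-05, adjusted p = 0.79 with an estimated correlation), matrix (-0.29, 0.000118, adjusted p = 0.673 with an estimated correlation) and fibroblast genes (-0.51, 0.00368, adjusted p = 0.82 with an estimated correlation) had lower ones. The MHC class I call was lost without air month 1 replicate 1 (0.335) or 2 (0.0969) or smoke month 1 replicate 1 (0.264). The MHC class II call was lost without air month 1 replicate 1 (0.0965) or smoke month 1 replicate 4 (0.0624), and the fibroblast call without air month 6 replicate 4 (0.0877) or smoke month 6 replicate 2 (0.267). With the replicate block erythroid and platelet genes passed as well (-0.73, 0.0438; adjusted p = 0.738 with the block and an estimated correlation), and of the 3 genes Pcdhgb8 did not pass. Month, age and lane cannot be told apart here. The count was 7 without air month 1 replicate 2, 6 without smoke month 1 replicate 2, 5 without air month 6 replicate 1, 15 with no filter on low counts (6 higher, 9 lower) and 58 with DESeq2 (22 higher, 36 lower). Of the genes that passed at months 1 and 6, only Cry2 was shared, against 0.0114 expected by chance (Fisher's exact p = 0.0114 over 14420 genes). This rests on 1 gene, which was no longer shared without any library of month 6 but air replicate 1, where its month 6 call was lost (adjusted p of up to 0.229).

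The smoke data were also asked whether genes changed by elastase moved in the same way. Genes higher at day 7 after elastase were slightly higher in smoke at month 1 (median 0.13, camera adjusted p = 0.032) and lower at month 6 (median -0.17, adjusted p = 1.04e-05). With at most 100 genes in a set these medians were larger, 0.23 and -0.52. Those higher at day 14 went the same ways (0.13 and -0.11, each adjusted p = 0.0215). Genes lower at day 7 were also lower at month 6 (-0.09, adjusted p = 0.0146). With an estimated correlation none of these passed (adjusted p = 0.603, 0.376, 0.657, 0.603 and 0.376 with an estimated correlation), and the other 5 sets did not pass. Cell cycle genes were among the highest at day 7, and their list also lay higher at month 1 and lower at month 6. The sets were not tested without cell cycle genes, so the result for genes higher at day 7 may repeat that of the list.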

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

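All tests of explanations in this part, the splits of the libraries included, were chosen after the results were seen.

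The first pattern is the rise of matrix genes after elastase, set against fibroblasts among the sorted cells. At day 7, 9 fibroblast markers outside the matrix list had a median log2 change of -0.36 (SD 0.517), and the 6 of them that encode no matrix protein one of -0.52 (SD 0.548). The matrix list stood at 0.51. The fibroblast list fixed before the data were examined had a median of -0.05, with 3 of 12 past the threshold and higher. Fibroblast markers thus did not rise in common with the matrix list. The 9 markers leave out Mfap5, which is on the matrix list, and Col1a1 and Col1a2, which are not. Of the 9 markers 0 passed the threshold, so the fibroblast markers that did pass at day 7 were among those left out. That choice lowers the median, so these markers cannot exclude more fibroblasts as the source. The medians do not speak to a change of expression within the fibroblasts present. At day 14 the same 9 and 6 markers stood at 0.53 (SD 0.15) and 0.48 (SD 0.15) beside a matrix median of 0.57, so more fibroblasts may account for part of the rise then (with either set as a covariate Eln, Mfap4, Mfap5 and Col3a1 kept 0.59 to 0.72 of their folds). The sort was set for purity, yet the fibroblast marker Inmt was present, at 164 ± 18.5 FPKM at day 14 and 125 ± 38.3 in controls. The epithelial marker Sftpc was higher still, at 1720 to 10600 FPKM in the elastase libraries. It lay above Cdh5 in every library, whose group means were 1191 to 1282. The share of other cells was not estimated. The lane cannot be told apart from the day at day 14, where the matrix median against day 7, in the lane of the controls, was 0.082. A response to elastase in the endothelium stays open at both times.

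The second pattern is the clock at month 6. The 11 clock genes of the Dbp phase had a median difference of 2.26 between smoke and air. They include Dbp, Tef, Hlf, Per3 and Cry2, which drew attention to the pattern, so this median describes it and tests nothing. The 6 genes of the opposite phase had a median of -0.96 (SD 1.186), with 4 lower, 2 higher and 0 past the threshold. The pan-endothelial list stood at -0.088, which argues against a lower share of endothelial RNA as the cause of that lower median. A different hour of collection in smoke and air mice could move both phases apart (-0.96 for the opposite phase), and it cannot be told apart from smoke because the labels give no hour. For Dbp it is the air group of month 6 that stands apart, with 169 CPM in smoke and 119 in air at month 1 and 157 and 4.87 at month 6. Arntl, of the opposite phase, was lower in smoke at both months, at 2.32 against 8.08 and at 10 against 41. All 11 genes of the Dbp phase were higher in smoke at month 1 too (median 0.51). The months also differ in lane and may differ in library kit. An effect of smoke on the clock stays open, and so does a shift in the air mice of month 6 that smoke had no part in.

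The third pattern is the wide spread of low genes at month 1. The ratio of variance to mean at mean counts of 5 to 10 was 0.91 of that at 80 to 160, against 0.45 at month 6, which is consistent with few starting molecules that were each read many times. Fewer reads at month 1 are argued against, because month 6 counts thinned to the totals of month 1 reached only 0.23 of the spread at month 1. No biological explanation was tested for this pattern.

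Other splits of the libraries were fitted in the same way. Each elastase comparison of 3 against 3 has 10 splits, too few for a share under 0.05. The real split gave 363, 126 and 13 genes at days 7, 14 and 21 and 382 between days 14 and 7, with 0 as the highest of the others in each, and it was the only 1 with as many genes. Between days 21 and 14 it gave 1, and 2 of the 10 splits gave as many, the highest other giving 2. At month 1 the real split gave 15 genes and the highest other 1. Only 1 of 35 splits, the real one, gave as many, which is the smallest share possible. It argues against chance but does not exclude it. At month 6 the real split gave 11 and the highest other 1, with 1 of 35 as large, but most of these splits do not keep to the pairs. The 8 that part all pairs are too few for a share under 0.05; 1 of them gave as many, the real one, the others gave 0, and with the replicate block 0 against 56. For the difference between months, 4 of 100 relabelings gave as many as the real 3, the highest other giving 5, but these do not keep to the pairs of month 6. Of 100 relabelings that part all those pairs, 9 gave as many, the highest other giving 7. Of the others, 8 of 13 that keep the real month 6 split gave as many, and 0 of 86 that do not. Those that keep it still hold the month 6 difference between smoke and air. This share therefore cannot decide on chance, which is not excluded for this count.

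In 17 of 234 groups of 4 libraries, 1 library stood far from the rest, with a gap to the nearest of over 0.829 of the group's range. Chance gives about 1 in 20. In smoke at month 1 these were Trerf1 in replicate 3 (0.887 of the range) and, in replicate 4, Kdr (0.853), Lox (0.843) and the haemoglobin genes Hbb-bs (0.846) and Hba-a1 (0.853). In air at month 1 they were Kdr (0.867) and Ramp2 (0.835) in replicate 2, Birc5 (1, with 0.541 CPM in replicate 4 and 0 in the others), Cox8a (0.853) and Ndufs8 (0.94) in replicate 1 and Lox (0.916) in replicate 4. In smoke at month 6 they were Psmb9 (0.878) and Col4a1 (0.929) in replicate 1. In air at month 6 they were Vegfa in replicate 3 (0.908), Nid1 in replicate 2 (0.855), Myh11 in replicate 1 (0.85) and the library total of replicate 1 (0.845), at 40417842 counts.

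Effects that differed between groups by a test of the difference were as follows. Between the smoke effects of the months 3 genes differed, Dbp (4.51), Tef (2.37) and Pcdhgb8 (-8.76), the last chosen after its values were seen. The lists that differed were those of the unfolded protein response (0.50), MHC class II (0.51), oxidative phosphorylation (0.15), MHC class I (0.14), AHR targets (-1.93), cell cycle (-1.02), epithelial (-0.72), fibroblast (-0.51) and matrix genes (-0.29), and of these AHR targets alone passed with an estimated correlation. Between days 14 and 7 of elastase 382 genes differed, among them Inmt (1.26), C7 (1.25), Cdo1 (1.22), Pdgfra (1.18) and Npnt (1.15), and Fam64a (-2.56), Ube2c (-2.48), Top2a (-2.45), Ccnb2 (-2.42) and Mki67 (-2.30). Between days 21 and 14 1 gene differed, Klf10 (0.71).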

How the results depend on the processing

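The covariates of 9 fibroblast markers outside the matrix list and of the 6 without matrix proteins, the fit without replicate 1 of both month 6 groups and the replicate block with an estimated correlation were chosen after the data were seen, and the other alternatives before the data were examined. Where no reason is given, the cause was not tested. Gene counts without 1 library each ranged from 155 to 318 at day 7, 1 to 146 at day 14, 1 to 60 at day 21, 86 to 359 between days 14 and 7, 0 to 11 between days 21 and 14, 7 to 19 at month 1, 3 to 19 at month 6 and 2 to 7 for the difference between months. The numbers of lists ranged from 7 to 9, 7 to 13, 7 to 15, 3 to 8, 4 to 8, 7 to 13, 9 to 16 and 7 to 13. With only both groups in the fit, which leaves fewer samples, the genes were 224, 76 and 2 at days 7, 14 and 21, 186 between days 14 and 7 and 0 between days 21 and 14 (limma; 1369 at an unadjusted p under 0.05). Without a filter on low values or counts they were 55 at day 14, 4 at day 21, 0 between days 21 and 14 (1650 unadjusted), 65 at month 1, 23 at month 6 and 15 for the difference between months, and 8 lists passed between days 14 and 7. With the covariate of 9 markers, limma called 0 genes at day 14 (1043 unadjusted) and 5 at day 21, with 4 lists at day 21. With that of 6 markers it called 206 genes at day 7, 0 at day 14 (909 unadjusted) and 4 at day 21, with 4 lists at day 21. Quantile normalization gave 226 at day 14, and a pseudocount of 0.1 gave 20 at day 21. DESeq2 gave 86 at month 1, 128 at month 6 and 58 for the difference between months, and was not run for lists. With all 16 libraries in 1 fit there were 63 genes and 7 lists at month 1 and 16 lists at month 6, and without replicate 1 of both groups 20 genes at month 6. The replicate block gave 56 genes at month 6, where the numbers pair the samples, and changed no other call there than those given beside that result. Elsewhere replicate numbers are only shared: same-numbered deviations correlated at -0.25 to 0.34 in the elastase experiment (5 of 12 libraries best with their own number) and at -0.05 to 0.07 at month 1 (0 of 8), and the block gave 28 genes at day 14 and 0 between days 21 and 14 (1303 unadjusted). With an estimated correlation 0 lists passed in camera in the 5 elastase comparisons and at month 6, and 1 each at month 1 and for the difference between months. With the replicate block and an estimated correlation it was again 0 at month 6 and 1 for the difference between months. The elastase gene sets then kept their medians of 0.13, -0.17 and -0.086 (day 7) and 0.13 and -0.11 (day 14) and did not pass. With at most 100 genes in a set the day 7 medians of higher genes were 0.23 and -0.52. Some list medians turned without 1 library. Those of MHC class I and II at day 7 ranged from -0.26 to 0.36 and from -0.81 to 0.66, with the lowest without day 7 replicate 3. That of aerocyte genes between days 21 and 14 reached 0.084 without day 21 replicate 1. That of inflammatory activation at month 6 ranged from -0.65 to 0.52, the highest without air replicate 1. For macrophage markers there camera gave the other direction without smoke replicate 2, though the median, 0.13 with all libraries and 0.41 then, kept its sign. With the covariate of 9 markers the day 14 medians of interferon, MHC class I, epithelial and mural genes were 0.45, 0.31, -0.14 and -0.21. With that of 6 markers they were 0.47, 0.33, -0.057 and -0.21, and that of MHC class I at day 7 was -0.26. Of the other refits of lists without 1 library, 1776 kept direction and side of the threshold, 93 came to pass and 73 no longer passed, and of those of named genes 468, 1 and 212. Named genes also lost their call in 21 tests with no filter on low values, 17 with only both groups in the fit, 29 with the covariate of 9 markers, 32 with that of 6, 19 with the replicate block, 6 with all 16 libraries in 1 fit and 1 without replicate 1 of both month 6 groups. The DESeq2 size factors changed no call in 96 list tests and 34 named gene tests. Depth is unknown in the elastase experiment, which leaves the counting error of low genes there unknown.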

Other observations

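The clock test below was chosen after the results were seen. Dbp was also higher 7 days after elastase, by 1.44 on the log2 scale (limma adjusted p = 0.0207), while the 9 clock genes of its phase, Dbp included, had a median change of 0.42 and 4 genes of the opposite phase one of -0.05. At days 14 and 21 the medians were 0.02 and 0.25 for the Dbp phase and 0.02 and 0.085 for the opposite one. At month 1 of smoke, 11 genes of the Dbp phase, again with Dbp, had a median of 0.51, with all 11 higher and 1 past the threshold. The 5 genes of the opposite phase had a median of -0.29, with 3 lower and 2 higher. At month 6, 5 of the 11 genes of the Dbp phase passed, all higher.

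Several endothelial programs had list medians that did not pass in camera. VEGF and angiogenic signalling genes stood at 0.004 at day 7 (adjusted p = 0.547), -0.02 at day 14 (0.99), -0.03 at day 21 (0.598), -0.09 at month 1 (0.4) and 0.001 at month 6 (0.851). General capillary genes stood at -0.08 at day 7 (0.272), -0.09 at day 14 (0.439), -0.02 at day 21 (0.546), -0.15 at month 1 (0.068) and -0.08 at month 6 (0.185). Venous genes lay between -0.03 and 0.08 in these 5 comparisons. Of the cell types outside the endothelium, T and NK cell markers did not pass in any of them.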
